A study of Mus musculus with 5 samples.

How the data were processed

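Single-cell RNA sequencing had been done on live CD45+ cells sorted from the dermis of C57BL/6 mice and captured in 10x Genomics droplets with 3' chemistry. There were 5 libraries, 1 for each label: P45, P50, P63, P80 and P50_Depil5D. The deposited matrices held whole-number UMI counts, so the unit is counts, with a list of Ensembl gene identifiers and symbols and a list of cell barcodes for each library. Per the labels, the reads were placed on the mm10 build, and Seurat is named without a version or a role. The aligner, the counting tool, the gene annotation and the rule for calling cells are not given in the sources used here. The table of 27998 genes was the same in all libraries, and 27645 of its identifiers were found in GENCODE vM21, from which coordinates were taken. It held no T cell receptor or immunoglobulin constant genes. Of the symbols asked for, it lacked Clec7a and Selenop among the lists and Acod1 among the markers. Members were matched by symbol only, so a gene listed under another symbol would be missed.

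Cells with at least 200 detected genes and at most 10% mitochondrial UMIs were kept, which removed 61 of 6223 barcodes, all for mitochondrial share. Scrublet (scanpy 1.11.5), run per library, marked 23 of the 6162 remaining cells, or 0.373%, as doublets. So low a share in a set of this size was taken as a sign that the caller missed doublets, which was not tested. The 23 cells were removed, and doublets must be taken to remain among the 6139 cells kept. An alternative removed the 41 further cells with a score over 0.2.

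Counts were scaled to 10000 per cell and log transformed. Genes detected in at least 3 cells were ranked by dispersion, 2000 were scaled and reduced to 30 principal components, and a graph of 15 exact nearest neighbours was clustered by the Leiden method at resolution 1 (igraph 0.11.9), keeping the partition of highest modularity among 500 random starts. All libraries were clustered together, without batch integration. Each cluster was named from markers of 19 classes fixed before the data were examined. A name needed at least 3 markers raised by a log2 fold of 1 over all other cells with at least 50 CPM. Of the classes so raised, the one with the highest mean fold gave the name. A cluster stayed unnamed where more of its 10 leading genes marked another class, where its first gene did, or where it was shallow and had no own marker among them. Unnamed clusters in which another class had 3 markers among the leading genes, or held the first of them, were clustered once more, which split 1 cluster into 7. The result was 36 clusters, 25 of them named in 10 classes, 6 of these immune, and 11 unnamed. Named clusters are called "like" their class. Some were led by genes that are not class markers. Alpha-beta T cell-like cluster 11 was led by Jchain, and T cell-like clusters 16 and 25 by cell cycle genes. NK cell-like cluster 10 was led by Gzmc and Ccl1, monocyte-like cluster 36 by Cxcl9 and Gbp2, and dendritic cell-like cluster 24 by unnamed gene models. Dendritic cell-like cluster 2 was led by Ccl22 and Ccr7, which are markers of its class, and then by the inflammatory gene Il1b. Pericyte or smooth muscle-like cluster 23 was led by Ccl21a and Fabp4. With 1 library per group, a cluster mostly of 1 library may be that library, not a type.

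The markers, gene lists, tests and the rule for naming genes were fixed before the data were examined. Several details of the clustering were not: leaving haemoglobin genes out, the number of random starts, the exact neighbour search, the order of naming, the leading-gene rule and the second round were settled after several earlier clusterings whose macrophage-like counts had been seen. They were chosen because they were stable over random starts and kept a cluster from carrying a name that its leading genes go against. The values without the second round and with 3 further sets of 500 starts stand among the alternatives.

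For each class and library, UMIs were summed over cells and expressed as CPM, counts per 1000000 UMIs of the class. A level has an exact 95% Poisson interval, a share of cells an exact 95% Clopper-Pearson interval, and a ratio of levels or shares an exact conditional 95% interval. These intervals cover counting error only, not differences between animals. A gene with 0 UMIs in 1 library was given a bound against a floor of 3 counts, set for each library and class. Log2 ratios have 10 CPM added to both values. With 1 library per group there is no test between time points or for depilation, and no p-value, standard error or number of changed genes was taken from cells. The same libraries underlie every class, so classes are not independent evidence.

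A list of genes was described by the median log2 ratio of its members and by the percentile of that median among 10000 random lists of the same size, drawn for each member from the 50 genes on either side of it in mean level. A list was said to stand apart when its percentile was under 2.5 or over 97.5. Its median was also taken over members with more than 3 UMIs in either library, those at 0 in 1 library being set at their bound, and members above and below 0 were counted there. There were 24 lists: oncostatin M (OSM) and related cytokines, OSM receptor and JAK-STAT components, STAT feedback and target genes, TREM2 and lipid-associated macrophage genes, resident dermal macrophage genes, monocyte-derived genes, inflammatory cytokines and the NF-kB response, alternative activation, type I interferon response, MHC class II presentation, phagolysosome, lipid and cholesterol handling, growth factors and morphogens acting on hair follicles, glycolysis and hypoxia, proliferation, immediate early and dissociation stress, regulatory T cell, type 2 lymphocyte, type 17 lymphocyte, cytotoxic lymphocyte, dendritic cell migration and maturation, mast cell granule, and, for RNA quality, ribosomal protein genes and mitochondrially encoded genes.

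In macrophage-like cells, the genes named for each contrast were the 12 with the highest and the 12 with the lowest log2 ratio among those with at least 100 CPM and at least 20 UMIs in the higher library and an interval of the ratio that excluded 1. For P80 over P45, the level also had to be ordered one way over P45, P50, P63 and P80. In any other class with at least 40 cells in both libraries, the 3 highest and the 3 lowest were named. Xist, Tsix, Y-linked, mitochondrial and ribosomal protein genes, gene models named Gm plus a number, and markers of another class were left out of the ranking. The minimum of 40 cells was read as applying to the other classes. List members given as examples, and unnamed clusters singled out in the text, were chosen after their values were seen. Macrophage-like cells were compared although only 20 were kept from P80 and 29 from P50_Depil5D, because the design is about them.

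Only 2 comparisons had the library as replicate and were tested across libraries by exact two-sided sign-flip permutation tests. The first compared Osm in macrophage-like cells with Osm in the other 5 immune classes pooled. The second compared the share of macrophage-like cells with an Osm UMI between cells with and without a Trem2 UMI, after thinning each cell to 1000 UMIs and leaving out shallower cells.

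Alternatives fixed beforehand changed the cell filter (at least 500 genes, at most 5% mitochondrial UMIs, every barcode kept), the clustering (resolution 0.5 or 2, each library alone, classes from each cell's markers without clusters, doublets kept, 1000 genes with 15 components, the TREM2 list left out of the variable genes), the scaling (TMM library sizes from edgeR 4.0.16 in R 4.3.3, means over cells, thinned cells), the added count (1 or 50) and a minimum level of list members (50 CPM), and left out each library in turn. Others were chosen after seeing the data: removal of barcodes shared between libraries (copies or all), removal of barcodes with a low ribosomal pseudogene share, the stricter doublet score, structural cells left out of the denominator, unnamed clusters added to the comparison, and the macrophage-like cluster held almost wholly by P45 left out. The pseudogene share of a cell is the percentage that 17 ribosomal pseudogenes take of the UMIs of these and their parent genes. A share was low when under 0.5 of the library's median.

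The method was tested on simulated Poisson counts with the depth of barcodes that had a UMI of each of C1qa, C1qb and C1qc. These were taken before filtering and clustering. The exact intervals assume such counts, so the rates do not cover UMIs gathered in a few cells. For P80 over P45, the interval excluded 1 for 39.4% of genes changed 2-fold, 87.7% of genes changed 4-fold and 3.15% of unchanged genes. For P50_Depil5D over P50 these shares were 62.7%, 98.0% and 4.25%. Of random lists of unchanged genes, 1.5% and 1.0% fell outside the middle 95%, and the sign-flip test gave its smallest p in 5.2% of 2000 data sets without a difference. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.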

Results

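Immune cells of mouse dermis were profiled by single-cell RNA sequencing of live CD45+ cells sorted from C57BL/6 skin. There were 5 libraries, 1 per group and without replicates: postnatal day 45 (P45), P50, P63 and P80, which follow the resting phase of the hair cycle, and P50_Depil5D, in which hair had been removed by depilation 5 days before. The labels do not say whether that skin was depilated or collected at P50. The libraries held 7491878 UMIs in 2153 barcodes (P45), 3242291 in 1479 (P50), 1882756 in 592 (P63), 1032621 in 497 (P80) and 3290482 in 1502 (P50_Depil5D). Median UMIs per barcode were 2543, 1435, 1888.5, 1249 and 1475, and the cells kept numbered 2138, 1456, 575, 487 and 1483.

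The libraries also differed in their barcodes and pseudogene counts, which with 1 library per group cannot be told apart from the groups. Of the cells kept, 191 in P50, 195 in P63, 246 in P80 and 176 in P50_Depil5D had a barcode that also occurred in another of these 4 libraries, whereas P45 shared at most 7 barcodes with any of them. The median share of ribosomal pseudogenes in the UMIs of these and their parent genes was 10.2% in P45, 4.17% in P50, 24.2% in P63, 29.5% in P80 and 4.17% in P50_Depil5D, and cells under 0.5 of their library's median made up 6.50%, 17.8%, 10.1%, 35.5% and 16.7%. In P63 and P80 these cells formed a separate peak, while in P50 and P50_Depil5D they were the lower end of a single one, with 71 and 68 cells close to the limit. Cells under 0.5 of their library's median are called low-share cells here, and values without them are given where they matter. Of the low-share cells, 58 of 58 in P63 and 144 of 173 in P80 had a shared barcode. In P50 these were 83 of 259 and in P50_Depil5D 63 of 247. Sharing was marked among these 4 libraries only, so the 139 low-share cells of P45 were not examined for it.

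**Figure D1:**
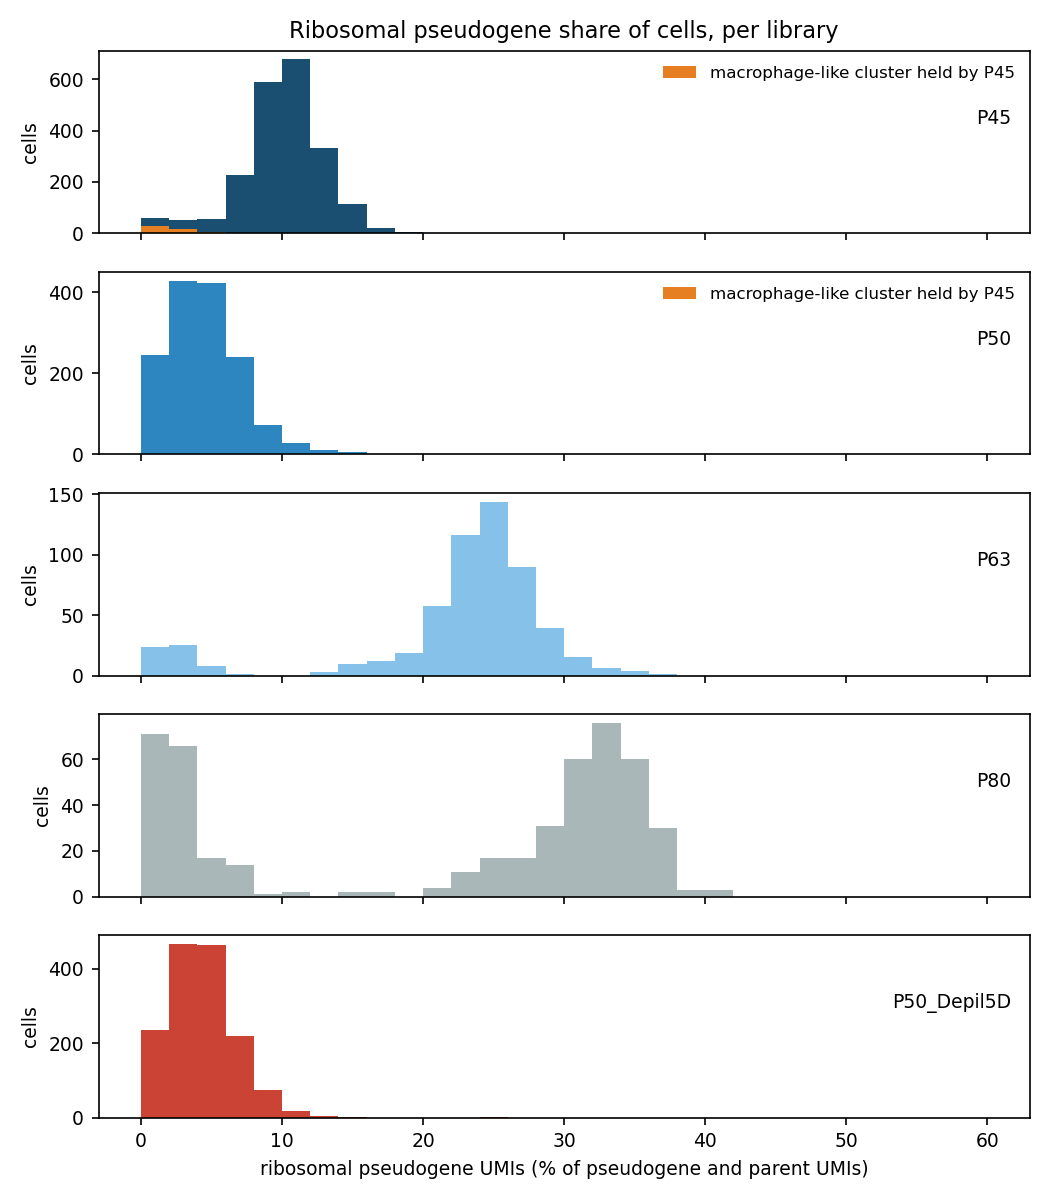
Histograms of the ribosomal pseudogene share of each kept cell (percent of pseudogene and parent UMIs, horizontal axis) against the number of cells, 1 panel per library, with the macrophage-like cluster held by P45 in orange. Medians were 10.2% in P45, 4.17% in P50 and P50_Depil5D, 24.2% in P63 and 29.5% in P80, where 35.5% of cells lay in a lower peak.

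The first question was how the makeup of the immune cells differed along the resting phase. Macrophage-like cells, defined by complement C1q genes, Mrc1, Pf4 and other fixed markers, made up 11.0% of the cells kept at P45 (95% interval 9.70 to 12.4), 6.80% at P50, 3.83% at P63 and 4.11% at P80 (2.53 to 6.27). Their share was 2.68-fold lower at P80 than at P45 (1.69 to 4.46). NK cell-like cells were also fewer, with 117 cells (5.47%) at P45 and 5 (1.03%) at P80. Dendritic cell-like cells, which carry antigen to lymph nodes, made up 25.8% at P45 and 18.1% at P80, and alpha-beta T cell-like cells 7.11%, 17.9%, 15.8% and 8.62% in order of age. Of the 260 T cell-like cells of P50, 55 were in cluster 16, which had 2, 1 and 2 cells in P45, P63 and P80. Its levels of Ctla2a, Areg and Cd3e (10886, 1854 and 3886 CPM) were close to those of the unnamed cluster 0 (15494, 2767 and 4234). Cluster 13, with 78 cells in P50, had 7995, 293 and 4070. Clusters 13 and 16 were named from Cd3e, Cd3d, Cd3g and Lat alone, the 4 markers also raised in cluster 0. These markers do not tell alpha-beta from gamma-delta T cells.

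Keratinocyte-like cells, which a CD45 sort should exclude, were 11.4% of cells at P45, 13.7% at P50, 35.7% at P63 and 45.2% at P80. They lower every other share. In cluster 8, 3 of 24 cells were low-share at P45, 25 of 27 at P63 and 64 of 67 at P80. In cluster 4 these numbers were 4 of 134, 14 of 101 and 18 of 79. Part of the higher keratinocyte-like share at P63 and P80 thus rests on low-share cells. With keratinocyte-like, fibroblast-like, pericyte-like and neural crest-like cells left out of the denominator, the P80 over P45 ratio was 0.605 (0.363 to 0.956) in place of 0.374 for macrophage-like cells, 1.96 in place of 1.21 for T cell-like cells, and 1.13 in place of 0.700 for dendritic cell-like cells, whose direction was thus the opposite. The dendritic cell-like ratios leave out unnamed clusters 5, 7 and 20, in which dendritic cell markers were raised. These held 254, 180 and 43 cells at P45 and 4, 20 and 3 at P80. Counting them as dendritic cells would lower the ratio of 1.13, so the opposite direction holds for the named clusters only. Without low-share cells the macrophage-like ratio was 0.633 (0.367 to 1.03), an interval that includes 1. Over all alternatives, these included, the ratios were 0.227 to 0.633 for macrophage-like, 0.487 to 1.13 for dendritic cell-like and 0.726 to 1.98 for T cell-like cells. Langerhans cell-like cells (0.982% and 0.821%) and monocyte-like cells (0.702% and 1.03%) did not differ between P45 and P80 beyond counting error in the main analysis. However, the 4 Langerhans cell-like cells of P80 were all low-share. Without low-share cells, or without copies of shared barcodes, P80 had 0 such cells and P45 had 21. The NK cell-like ratio of 0.188 was 0.732 (0.222 to 1.90) with classes read from the markers of each cell, an interval that includes 1. That of monocyte-like cells, 1.46, turned direction with an interval that excluded 1 at resolution 2 (0.384, upper end 0.829), with doublets kept (0.146, 0.00359 to 0.880) and with fewer variable genes (0.403, 0.261 to 0.599). Unnamed clusters held 33.4% of cells at P45, 36.4% at P50, 19.3% at P63, 18.5% at P80 and 41.5% in P50_Depil5D.

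**Figure D2:**
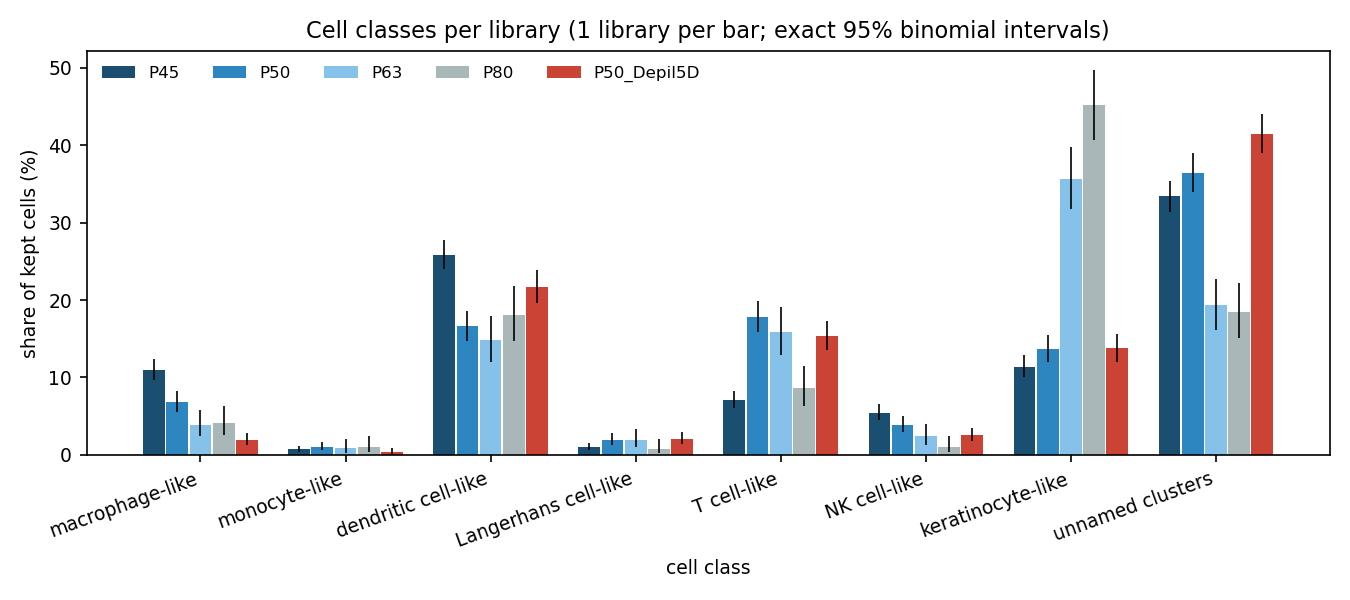
Share of kept cells (percent, vertical axis) in each named class and in the unnamed clusters, with 1 bar per library and exact 95% binomial intervals. Macrophage-like cells were 11.0% at P45 and 4.11% at P80, and 6.80% at P50 against 1.96% in P50_Depil5D. Keratinocyte-like cells reached 45.2% at P80, with low-share cells among them.

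After depilation the macrophage-like share was 3.48-fold lower (2.28 to 5.46): 29 of 1483 cells (1.96%, 1.31 to 2.80) in P50_Depil5D against 99 of 1456 (6.80%, 5.56 to 8.22) in P50. Dendritic cell-like cells were a larger part after depilation, 21.7% against 16.6%, a ratio of 1.31 (1.10 to 1.55). Unnamed clusters 5, 7 and 20 are not in this ratio. They held 26, 33 and 13 cells in P50_Depil5D and 28, 55 and 22 in P50, and would narrow this difference if counted with the dendritic cells. T cell-like cells made up 15.3% and 17.9%, NK cell-like cells 2.56% and 3.85%, Langerhans cell-like cells 2.09% and 1.92%, monocyte-like cells 0.405% and 1.03%, and keratinocyte-like cells 13.8% and 13.7%. None of these 5 differed beyond counting error in the main analysis. The T cell-like ratio of 0.857 was 1.09 at resolution 0.5, 1.07 with markers read per cell and, with each library clustered alone, 1.27 (1.05 to 1.54), an interval that excludes 1 in the opposite direction. The ratio of 0.857 leaves out unnamed cluster 0, which held 18.5% of cells in P50 and 25.4% in P50_Depil5D. Cluster 0 had the same 4 markers raised as T cell-like clusters 13 and 16. The macrophage-like difference rested on the clustering, since the alternatives gave ratios of 0.246 to 0.840. With each library clustered alone, neither the macrophage-like ratio (0.840, 0.643 to 1.10) nor the dendritic cell-like ratio (1.04, 0.891 to 1.21) differed from 1 beyond counting error. An unnamed cluster of 57 cells, number 31, led by Cxcl2, Cd14 and Il1rn and with C1qb, Adgre1 and Trem2 raised, held 28 cells (1.89%) in P50_Depil5D and 20 (1.37%) in P50 and would narrow the difference if counted with the macrophages.

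Which cells carry oncostatin M was the next question. Osm (ENSMUSG00000058755, mm10 chromosome 11, 4236420 to 4241026) encodes a cytokine of the interleukin-6 family that acts through JAK-STAT signalling. Pooled over libraries, its level was 65.0 counts per 1000000 UMIs (CPM; 95% interval 49.9 to 83.4; 62 UMIs in 405 cells) in macrophage-like cells and 64.7 (26.0 to 133; 7 UMIs in 46 cells) in monocyte-like cells. Without P45 these levels were 39.2 (21.4 to 65.8; 14 UMIs) and 79.4 (29.1 to 173; 6 UMIs), and the 6 monocyte-like UMIs were from P50 (146 CPM). Dendritic cell-like cells had 13.5, T cell-like cells 12.5, Langerhans cell-like cells 9.37 and NK cell-like cells 0 (0 to 7.50, in 230 cells). An Osm UMI was found in 9.14% of macrophage-like cells (median depth 2078 UMIs) and in 0.187% of keratinocyte-like cells (median depth 2724 UMIs), a class set as the comparison that should lack the gene. Per library, 10.6%, 6.06%, 4.55%, 10.0% and 10.3% of macrophage-like cells had one in P45, P50, P63, P80 and P50_Depil5D. After thinning each cell to 1000 UMIs the shares were 4.68% in P45, 6.17% in P50 and 3.70% in P50_Depil5D, with 0 of 22 cells in P63 (up to 15.4%), 0 of 7 in P80 (up to 41.0%) and no keratinocyte-like cell in any library.

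Within each library, macrophage-like cells had a higher Osm level in CPM than the other immune classes pooled: 80.5 against 8.03 in P45, 36.8 against 25.7 in P50, 22.1 against 4.95 in P63, 87.1 against 9.46 in P80 and 42.1 against 11.9 in P50_Depil5D. The mean log2 difference was 1.48, positive in 5 of 5 libraries, with an exact two-sided sign-flip p of 0.0625, the smallest that 5 libraries can give, so that this design cannot reach 0.05. Counting error alone excluded a ratio of 1 in P45, where it was 10.0 (5.78 to 18.0), and not in P50 (1.43, 0.570 to 3.17), P63 (4.46, 0.0756 to 85.7), P80 (9.20, 0.667 to 127) or P50_Depil5D (3.54, 0.661 to 12.4). Of the 48 Osm UMIs of P45 macrophage-like cells, most came from cluster 32, which had 51 cells in P45, 1 in P50 and 0 elsewhere, and of whose P45 cells 48 were low-share. This cluster had 329 Osm CPM and the other P45 macrophage-like cells 20.7 (9.95 to 38.1). The mean log2 difference was 1.17 without the cluster and 1.18 without low-share cells, and 2 unnamed clusters had levels above that of the macrophage-like class: 117 in cluster 31 and 133 in cluster 33, which was led by S100a9, Ngp and S100a8.

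**Figure D3:**
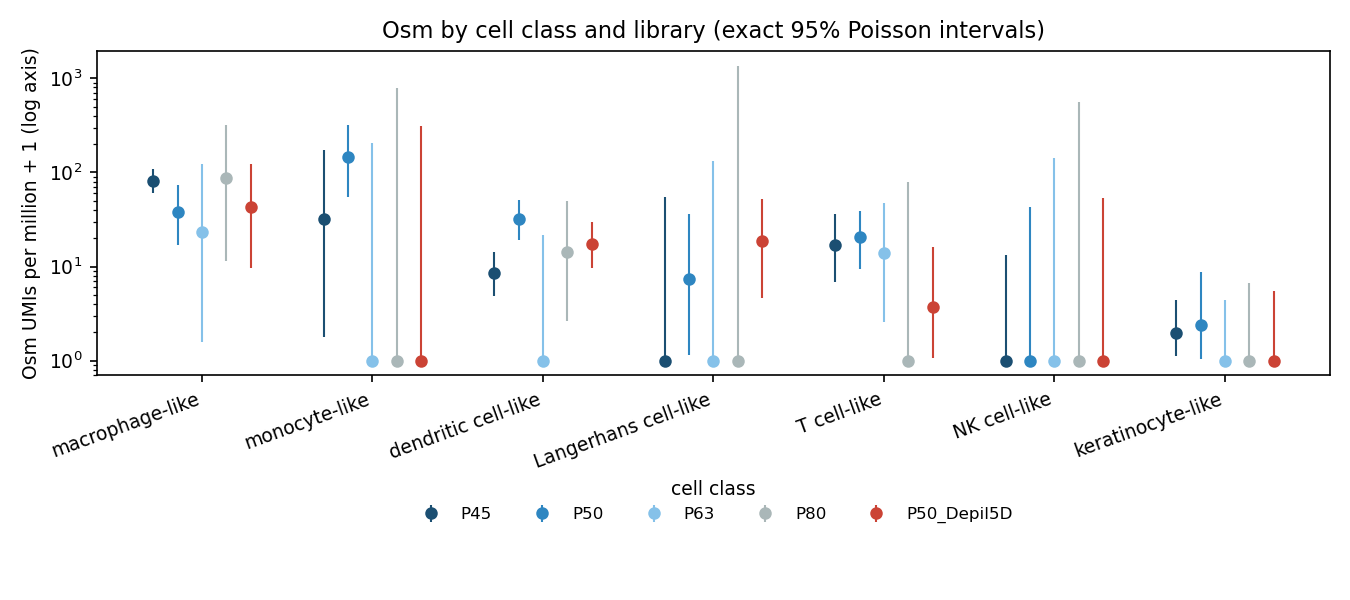
Osm level (CPM plus 1, logarithmic vertical axis) in each class and library, with exact 95% Poisson intervals; a point at 1 has 0 UMIs. Macrophage-like cells had 80.5 in P45, 36.8 in P50, 22.1 in P63, 87.1 in P80 and 42.1 in P50_Depil5D.

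TREM2, a lipid-sensing receptor of macrophages, marks a macrophage state in the fixed lists, and the share of cells with Osm was compared between macrophage-like cells with and without a Trem2 UMI. Trem2 (ENSMUSG00000023992, mm10 chromosome 17, 48346401 to 48354147) had 307 CPM in macrophage-like cells, 5.96 in dendritic cell-like cells and 0 in T cell-like cells. In P45, after a separate random thinning, 22.0% of 41 cells with Trem2 had an Osm UMI (10.6 to 37.6) and 3.09% of 194 without. In P50 the shares were 10.0% of 20 and 3.28% of 61, in P63 0 of 2 cells (up to 84.2%) and 1 of 20, and in P50_Depil5D 0 of 7 (up to 41.0%) and 0 of 20 (up to 16.8%), with 18, 0 and 2 cells left out as too shallow. P80 kept 7 cells, none with Trem2, and lost 13. The mean difference over 4 libraries was 5.14 percentage points, positive in 2, negative in 1 and 0 in 1 (exact two-sided sign-flip p of 0.5). The smallest p of this test with 4 libraries is 0.125, which the difference of 0 put out of reach. Without thinning the mean difference was 4.26 points over 5 libraries (3 positive and 2 negative, exact sign-flip p of 0.562). The shares were 29.3% against 4.52% in P45, 13.8% against 2.86% in P50, 0 of 2 cells against 1 of 20 in P63, 0 of 1 against 2 of 19 in P80 and 1 of 9 against 2 of 20 in P50_Depil5D. The difference rested on P45 and its cluster 32: it was 0.574 points without P45 and 0.272 without the cluster, -0.987 under another set of random starts and -0.315 with cells thinned to 500 UMIs. It was larger without P63 (8.53 points) and without the second round of clustering (21.7).

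Along the resting phase, Osm in macrophage-like cells stood at 80.5 CPM at P45 (59.3 to 107), 36.8 at P50 (15.9 to 72.4), 22.1 at P63 (0.560 to 123) and 87.1 at P80 (10.5 to 315), the last from 2 UMIs in 20 cells. A difference between P80 and P45 was not detectable in the main analysis, with a ratio of 1.08 (0.127 to 4.13). Without cluster 32 the ratio was 4.20 (0.447 to 19.7), and without low-share cells, which left 33.3 CPM at P45, it was 2.79 (0.312 to 11.9). Without the second round of clustering it was 11.2 (1.01 to 78.1), an interval that excludes 1, so that whether a difference was seen depended on the clustering. Depilation gave no detectable difference either: 42.1 CPM (8.68 to 123; 3 UMIs) in P50_Depil5D and 36.8 in P50 (8 UMIs), a ratio of 1.14 (0.196 to 4.77) that lay between 0.572 and 3.63 over the alternatives. TMM scaling lowered each P80 over P45 log2 ratio in macrophage-like cells by 0.68 and each P50_Depil5D over P50 ratio by 0.16, so a P80 over P45 ratio between 1 and 1.60 fell below 1 with it.

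The macrophage-like state was then compared between P80 and P45. Genes of the TREM2 and lipid-associated state and of phagolysosomes had lower levels at P80 by their medians, and the kinase gene Pim1 had a higher one. Lists of lipid handling and monocyte-derived genes also had low medians, but these were 0.00 with members at their bound. Most macrophage-like cells were in cluster 9 in both libraries (143 of 235 cells at P45, 15 of 20 at P80), followed by clusters 32 and 30 at P45 (51 and 40 cells) and 30 at P80 (5 cells). P80 contributed 22967 UMIs and P45 596466, so genes with fewer than 3 UMIs at P80 had wide intervals.

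Of the TREM2 list, 5 members were above and 11 below 0, and the median log2 ratio was -1.09, lower than in each of 10000 random lists (-0.52 with members at their bound). Trem2 itself had 250 CPM at P45 (211 to 293) and 43.5 at P80 from 1 UMI, a ratio of 0.174 (0.00438 to 0.986). Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), encoding osteopontin, was at least 1.80-fold lower (0 UMIs at P80 and 140 at P45). The lipase gene Lpl had a ratio of 0.109 (0.00275 to 0.614), the protease gene Ctsd one of 0.168 (0.0344 to 0.493), and the lipid carrier gene Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188) one of 0.480 (0.415 to 0.552), with 18055 and 8665 CPM. In P50 and P63, Trem2 stood at 533 and 44.2 and Spp1 at 460 and 0. Cluster 32 weighed on these values: it had 910 CPM of Trem2, 1136 of Spp1, 3216 of Ctsd and 65503 of Apoe. The other P45 macrophage-like cells had 91.3, 18.7, 201 and 6676. The list's median was -0.59 without that cluster and -0.84 without low-share cells, where the Apoe ratio was 1.12 (0.962 to 1.29), and it no longer stood apart with cells of at least 500 genes (-0.43) or without the second round of clustering (-0.28).

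**Figure D4:**
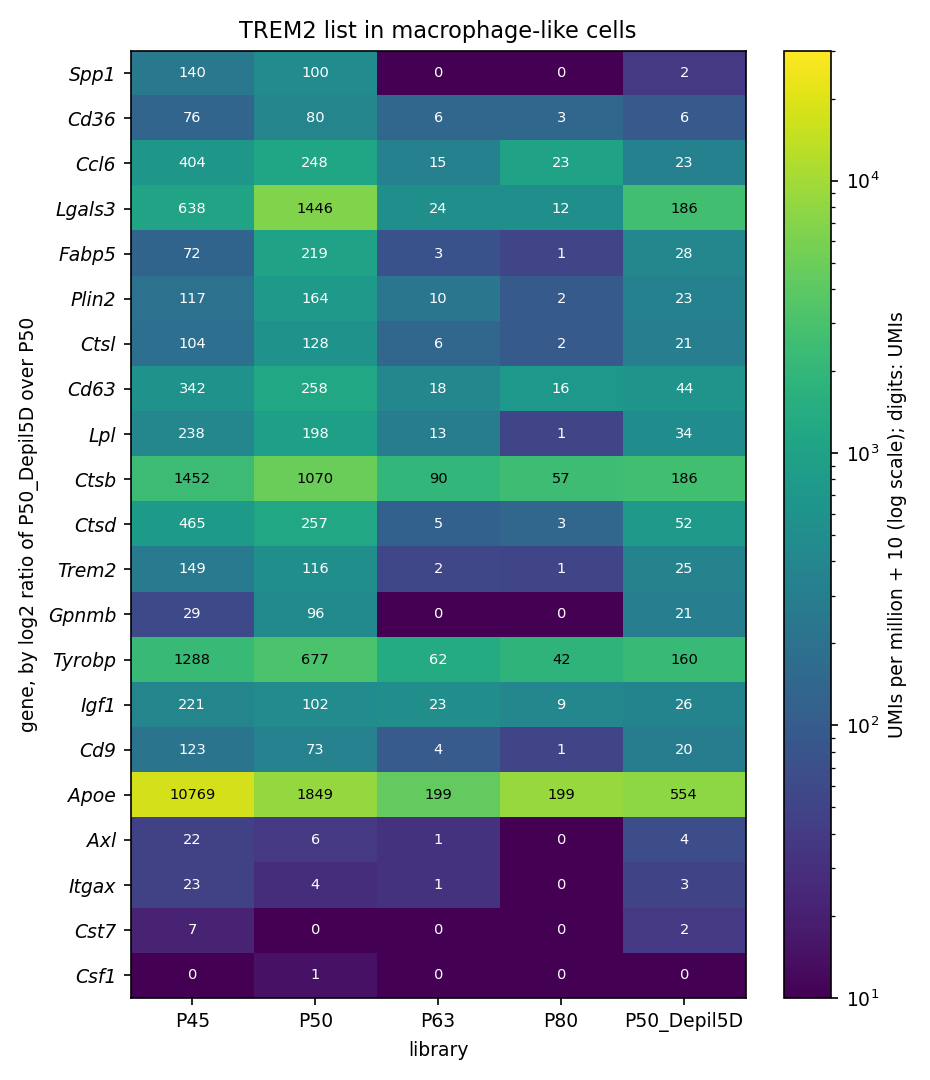
CPM plus 10 (colour, logarithmic scale) of the members of the TREM2 and lipid-associated list in macrophage-like cells of each library, with the UMI count in each box and genes in order of their P50_Depil5D over P50 ratio. Spp1 had 140 UMIs in P45, 100 in P50, 2 in P50_Depil5D and 0 in P63 and P80.

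Other groups of genes also set P80 apart from P45 in macrophage-like cells. The monocyte-derived list had a median of -1.51 (0.00 at the bound, 1 member above and 4 below), with the chemokine receptor gene Ccr2 at least 1.73-fold lower. The phagolysosome list had a median of -0.53 (-0.27 at the bound, 5 above and 10 below), with the protease gene Ctss at a ratio of 0.482 (0.289 to 0.756). Lipid and cholesterol handling had -1.01 (0.00 at the bound, 3 above and 6 below), glycolysis and hypoxia -0.61 (-0.17 at the bound, 3 above and 7 below), although Hmox1, which breaks down haem, was 3.71-fold higher (2.26 to 5.82), and cytotoxic lymphocyte genes -0.50 (0.00 at the bound, 0 above and 2 below). STAT feedback and target genes had a median of 0.19, above 99.9% of random lists (0.60 at the bound, 5 above and 0 below). The median was -0.17 with TMM scaling, which lowers every log2 ratio here alike, and -0.41 with 1 added in place of 10. It still lay above 99.92% and 99.85% of random lists. Within this list, Pim1 was 4.92-fold higher (3.64 to 6.55) and the feedback inhibitor gene Socs3 2.69-fold higher (1.35 to 4.87). Of the 57 Pim1 UMIs at P80, 20 were in 1 cell, though 16 of the 20 cells had one. Ribosomal protein genes stood apart as well with a median of -0.28, in libraries whose ribosomal pseudogene shares differed (29.5% in P80 and 10.2% in P45), while mitochondrial genes were at 0.05 (-0.63 with TMM scaling). Thus 8 of 24 lists stood apart, and 4 did without low-share cells.

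No shift beyond that of random lists was found for the other lists. Medians were 0.34 for immediate early and dissociation stress genes (percentile 97.4), 0.23 for resident dermal macrophage genes, 0.16 for alternative activation and 0.15 for MHC class II presentation, and with TMM scaling these were -0.32, -0.36, -0.51 and -0.52. Inflammatory cytokines and the NF-kB response had -0.32, with the chemokine genes Ccl4 4.69-fold (3.34 to 6.47), Ccl7 2.01-fold and Ccl2 1.98-fold higher. OSM receptor and JAK-STAT components had -0.23, OSM and related cytokines 0.00, type I interferon response -0.59, growth factors and morphogens 0.00, proliferation -0.41, regulatory T cell -0.66, type 2 lymphocyte -0.22, type 17 lymphocyte -0.22, dendritic cell migration and maturation -0.66 and mast cell granule genes -0.22.

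Of single genes with a level ordered over all 4 ages, 5 were higher at P80 by the fixed rule: Pim1, Ccl7, Csf1r (the receptor for colony-stimulating factor 1; 1.96-fold, 1.25 to 2.95), the noncoding RNA Malat1 (1.82-fold, 1.72 to 1.92) and Ly6e (1.76-fold, 1.30 to 2.34). Pim1 stood at 505 CPM at P45, 515 at P50, 1194 at P63 and 2482 at P80. The 12 lower genes included AF251705, Atp5a1 and Ywhab, which had no UMI at P80 and were at least 1.73-, 1.44- and 1.31-fold lower. Cathepsin H (Ctsh) had a ratio of 0.136 (0.0165 to 0.496), the peroxidase gene Prdx5 0.139 (0.00350 to 0.783), the translation factor genes Eif2s2 and Eef1a1 0.140 (0.00352 to 0.788) and 0.476 (0.320 to 0.682), and the chaperone gene Hsp90aa1 0.213 (0.0256 to 0.777). Son had 0.266, Ms4a6c 0.316 and the surface antigen gene Cd52 0.619. These directions were kept with TMM scaling, but the higher genes other than Pim1 then differed little. With it, the log2 ratios were 1.60 for Pim1, 0.33 for Ccl7, 0.29 for Csf1r, 0.18 for Malat1 and 0.14 for Ly6e.

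After depilation, macrophage-like cells had lower levels of TREM2-state, phagolysosome, lipid-handling, resident-macrophage and interferon-response genes than at P50, and higher levels of inflammatory, MHC class II and immediate early genes. Il1b, encoding the inflammatory cytokine interleukin-1 beta, had 1543 CPM after depilation and 193 in P50, a difference of 5.56- to 11.7-fold by its interval (110 UMIs in 29 cells against 42 in 99), and Spp1 was 16.4-fold lower (4.42 to 137; 2 against 100 UMIs), although without the second round of clustering its log2 ratio was 1.72 in place of -3.62. In P50 the cells lay in clusters 9, 34 and 30 (56, 32 and 10 cells), and in P50_Depil5D in the same clusters (15, 9 and 5). In all, 10 of 24 lists stood apart, 5 above and 5 below, and 9 to 12 did under the alternatives tried.

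The TREM2 list had a median log2 ratio of -0.69, lower than in each of 10000 random lists (-0.91 at the bound, 2 members above and 17 below). Beside Spp1, the fatty acid transporter gene Cd36 had a ratio of 0.229 (0.0816 to 0.521), Ccl6 0.283 (0.176 to 0.435) and the galectin gene Lgals3 0.393 (0.335 to 0.458). Trem2 stood at 351 CPM (227 to 518) against 533 (440 to 639), a ratio of 0.658 (0.409 to 1.02) that counting error does not set apart from 1, and Apoe at 7773 against 8497. Phagolysosome genes had a median of -0.89 (-0.89 at the bound, 1 above and 16 below), with the lysosomal membrane gene Cd68 at 0.328 (0.201 to 0.510) and Ctsb at 0.531 (0.452 to 0.621). Lipid and cholesterol handling had -0.74 (-0.83 at the bound, 3 above and 10 below), with Fabp5 at 0.390 (0.253 to 0.580). Resident dermal macrophage genes had -0.54 (-0.47 at the bound, 1 above and 14 below), with Cd209f at 0.361 (0.196 to 0.618) and Folr2 at 0.472 (0.275 to 0.768). The lectin gene Cd209d was 2.28-fold higher, but 24 of its 59 UMIs after depilation were in 1 cell. The type I interferon response had -0.73 (-0.81 at the bound, 0 above and 8 below), with Ifi27l2a at 0.314 (0.238 to 0.407) and Isg15 at 0.321 (0.113 to 0.744).

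Higher after depilation were MHC class II presentation genes, with a median of 0.72 (6 members above and 1 below), including H2-DMa at 2.18-fold (1.63 to 2.92), H2-Ab1 at 1.97-fold (1.80 to 2.16) and the invariant chain gene Cd74 at 1.91-fold (1.80 to 2.02). Dendritic cell genes were higher with them: the fixed dendritic cell markers together had 1024 CPM against 625, a ratio of 1.64 (1.22 to 2.19), and Cd74 and Cd209d were leading genes of dendritic cell-like cluster 1 and Il1b of cluster 2. Doublets or dendritic cells among the 29 cells were not ruled out. Inflammatory cytokines and the NF-kB response had 0.52 (0.68 at the bound, 10 above and 3 below), with the NF-kB inhibitor gene Nfkbia at 1.91-fold (1.43 to 2.54) and the neutrophil attractant gene Cxcl2 at 1.68-fold (1.35 to 2.10), while Ccl4 had a ratio of 0.486 (0.255 to 0.859). Immediate early and dissociation stress genes had 0.55 (15 above and 2 below), with Ier3 at 2.58-fold (1.48 to 4.44) and Jun at 1.80-fold (1.24 to 2.60), and such genes also answer to tissue digestion. Proliferation genes had 0.01 (0.14 at the bound, 5 above and 0 below), with the histone gene H2afz at 2.20-fold (1.68 to 2.89), and ribosomal protein genes 0.16. Mitochondrial genes (0.32) and STAT feedback and target genes (0.30) were close to the edge of the random lists, at percentiles of 97.3 and 97.2. Alternative activation had -0.51, monocyte-derived genes -0.07, glycolysis and hypoxia 0.01 (-0.08 with TMM scaling) and OSM receptor and JAK-STAT components 0.09, none standing apart. The median was 0.00 for OSM and related cytokines, growth factors and morphogens, regulatory T cell, type 2, type 17 and cytotoxic lymphocyte, dendritic cell migration and maturation, and mast cell granule genes, most of whose members had too few UMIs to be compared.

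By the fixed rule, 12 single genes were higher and 12 lower after depilation. Besides Il1b, Ier3 and Cd209d, the higher ones included the elastase gene Mmp12 (7.25-fold, 3.95 to 13.9), Avpi1 (6.36-fold, 3.08 to 13.9), the interleukin-1 receptor antagonist gene Il1rn (3.33-fold, 1.79 to 6.23), the proteoglycan gene Srgn (2.71-fold, 1.90 to 3.86), Napsa (2.69-fold), Erh (2.58-fold), Tppp3 (2.56-fold) and S100a11 (2.29-fold). The first by rank, Scgb1a1, a secretory gene of airway epithelium, had all of its 40 UMIs in 1 cell. Mmp12 had its 38 UMIs in 5 cells, and its log2 ratio of 2.70 was -0.94 with every barcode kept, -0.98 with fewer variable genes, -0.96 without the second round of clustering and -0.82 with another set of starts. Il1rn had 11 of its 24 UMIs after depilation in 1 cell, and its log2 ratio was -0.17 without that second round. Among the lower genes, Rbm8a was at least 2.84-fold lower (0 against 26 UMIs), and Mpp1, Rab5c, Tslp, Tnfsf12, Zbp1, Lamtor4, Snx8, Dnase2a and Txnl1 had ratios of 0.0985 to 0.145 from 1 or 2 UMIs in P50_Depil5D. Retnla, a marker of alternative activation, had a ratio of 0.105 (0.0568 to 0.178), but its 14 UMIs were in 1 of 29 cells and its 408 UMIs in 8 of 99. Its log2 ratio of -3.19 was 0.20 with at most 5% mitochondrial UMIs, 0.13 with each library clustered alone and 0.21 with doublets kept.

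Dendritic cell-like cells at P80 had 4 lists apart from P45: lower dendritic cell migration and maturation (-0.51), alternative activation (-0.32) and ribosomal protein genes (-0.35), and type I interferon response genes at 0.00, above 98.4% of random lists. Irf8, a transcription factor gene of type 1 dendritic cells, was 19.1-fold lower (5.26 to 159) and Id2 5.31-fold lower (2.42 to 14.6), with Bcl2a1b 7.71-fold lower (2.10 to 64.2). Ccl7 was 13.6-fold higher (9.49 to 19.5), although 54 of its 74 UMIs were in 1 cell, and Gclm and Tomm6 7.09-fold and 6.34-fold higher. However, 56 of the 88 P80 cells were in cluster 24, which had 0 cells in P45 and was led by unnamed gene models and the ribosomal pseudogene Rps18-ps3, whereas P45 cells were in clusters 2, 1 and 15 (271, 199 and 82 cells). Without low-share cells 1 list stood apart, and TMM scaling, which lowered log2 ratios by 0.25, or 50 added in place of 10 left 2.

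After depilation, dendritic cell-like cells had lower immediate early genes (-0.29, 1 member above and 16 below; -0.09 with TMM scaling, which raised log2 ratios by 0.21) with Fos at 0.524 (0.464 to 0.592). Proliferation genes were at -0.21, with Stmn1 at 0.487 (0.279 to 0.836), and ribosomal protein genes at 0.08. The chemokine gene Ccl17 was 6.56-fold lower (4.69 to 9.37), with 101 of 207 UMIs in P50 and 21 of 42 after depilation in 1 cell each, the interferon-induced gene Ifitm3 3.15-fold lower and Sept11 2.40-fold lower. Ccl5 was 6.47-fold higher (4.11 to 10.7), with 71 of 181 UMIs in 1 cell, and Odc1 and Tcea3 2.90-fold and 2.64-fold higher. Clusters 1 and 2 held most of these cells in both libraries.

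In T cell-like cells, 4 lists were lower at P80 than at P45: MHC class II presentation (-0.96, H2-Ab1 at a ratio of 0.346), monocyte-derived (-0.85, Plac8 at 0.117), dendritic cell migration and maturation (-0.64) and ribosomal protein genes (-0.52). These include genes of other cell types. Lrrc58, Spry2 and the keratinocyte gene Lgals7 were 6.70-fold, 4.81-fold and 4.33-fold higher in P80, the library with the largest keratinocyte-like share. The plasma cell genes Jchain and Mzb1 were at least 37.3-fold and 3.50-fold lower, but the 873 Jchain UMIs of P45 lay in 4 cells. Without low-share cells the log2 ratio was 0 in place of -7.88 for Jchain and -2.59 in place of -4.52 for Mzb1. Stx16 was at least 1.71-fold lower. TMM scaling lowered the P80 over P45 log2 ratios of T cell-like cells by 0.47, and 7 lists stood apart without low-share cells. Most P45 cells were in clusters 11, 13 and 14, most P80 cells in 13 and 11. After depilation, T cell-like cells had higher immediate early genes (0.29, 14 above and 3 below), with Hspa1a at 2.31-fold (1.98 to 2.69), and ribosomal protein genes at 0.04, and 1 list stood apart without the copies of shared barcodes. Cd8b1, a co-receptor gene of cytotoxic T cells, was 5.83-fold higher (3.02 to 12.3) and Phlda1 2.40-fold. Dctpp1, Asf1b and Ube2m had ratios of 0.275, 0.375 and 0.375.

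Keratinocyte-like cells had 9 lists apart at P80. Proliferation genes were higher, with a median of 0.66 (13 above and 2 below), Ccnb1 at 6.02-fold (3.11 to 12.1) and Cdk1 at 4.71-fold (2.72 to 8.27), as were STAT feedback and target genes (0.43, Irf1 at 1.94-fold and Pim1 at 1.63-fold), resident macrophage genes (0.19) and mitochondrial genes (0.31). Lower were monocyte-derived (-0.42), lipid and cholesterol handling (-0.24), TREM2 (-0.22), phagolysosome (-0.13) and ribosomal protein genes (-0.20). The lipid synthesis gene Scd1 was 26.9-fold lower (14.1 to 59.0) and the fatty acid binding protein gene Fabp5 14.9-fold lower, with 40.1% and 41.9% of their P45 UMIs in 1 cell. Ccl27b, Cenpa and Serpinb2 were 4.28-fold, 5.18-fold and 3.79-fold higher. Cluster 4 held the most keratinocyte-like cells in both libraries (134 and 79), followed at P80 by cluster 8 (67, of which 64 were low-share). After depilation, 5 lists stood apart: higher proliferation (0.38, Mki67 at 2.36-fold), glycolysis and hypoxia (0.33, Hif1a at 1.76-fold) and NF-kB response genes (0.12, Nfkbia at 1.62-fold), and lower immediate early genes (-0.31) and MHC class II genes (-0.93). Of the last, H2-Ab1, Cd74 and H2-Eb1 had ratios of 0.245, 0.277 and 0.324, with 64.1%, 66.3% and 60.4% of their P50 UMIs in 1 cell. Serpinb2, the gap junction gene Gja1 and Crem were 3.90-fold, 3.95-fold and 3.65-fold higher.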

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

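The alternatives that removed shared or low-share barcodes, used the stricter doublet score, left out cluster 32, added unnamed clusters, left structural cells out of the denominator, left the mixed cluster whole or took other random starts were chosen as tests after the results had been seen; the others were planned. Of 365 values for 26 main results, 323 moved by less than counting error or kept their standing, 37 moved further, 3 reversed and 2 no longer stood apart. Of the 325 of these that have a direction, 28 lay on the other side of 1 or 0 from the main value. Of 887 values for 77 named genes, 878 kept their direction and 9 reversed. Of 950 values for 190 other lists, 892 kept their standing, 21 came to stand apart, 35 ceased to and 2 (the STAT list) were counted as reversed. In those 2 the sign of the median turned, while the list stayed above 99.85% and 99.92% of random lists. In all, 37 medians turned sign. Share ratios are given below for P80 over P45 (resting) or P50_Depil5D over P50 (depilation), genes and lists as log2 ratios in macrophage-like cells.

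With at least 500 genes per cell, the resting TREM2 median was -0.43. With at most 5% mitochondrial UMIs, the resting ratios were 0.726 for T cell-like and 0.550 for dendritic cell-like cells, and Retnla after depilation had 0.20. With every barcode kept they were 0.753 and 0.487, and Mmp12 had -0.94. At resolution 0.5 the depilation ratio was 1.09 for T cell-like and 0.505 for macrophage-like cells, and the resting ratio 0.542 for dendritic cell-like cells. At resolution 2 the resting ratios were 0.547 for dendritic cell-like and 0.384 for monocyte-like cells, and the depilation ratio 0.532 for macrophage-like cells. With each library clustered alone the depilation ratios were 1.27 for T cell-like, 1.04 for dendritic cell-like and 0.840 for macrophage-like cells, and Retnla had 0.13. With markers read per cell the resting ratios were 0.732 for NK cell-like and 0.809 for T cell-like cells, and the depilation ratios 1.07 for T cell-like and 0.459 for macrophage-like cells. With doublets kept the resting ratios were 0.509 for dendritic cell-like and 0.146 for monocyte-like cells, and Retnla had 0.21. With 1000 variable genes and 15 components they were 0.531 and 0.403, and Mmp12 had -0.98.

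Without shared barcodes the resting ratios were 1.98 for T cell-like and 0.604 for macrophage-like cells. Without low-share barcodes they were 1.77 for T cell-like, 0.892 for dendritic cell-like and 0.633 for macrophage-like cells, and in these classes 7, 1 and 4 lists stood apart. Without structural cells in the denominator they were 1.96, 1.13 and 0.605. The resting Osm ratio was 4.20 without cluster 32 and 11.2 (1.01 to 78.1, which excludes 1) with the mixed cluster not split, where the TREM2 median was -0.28 and depilation gave Mmp12 -0.96, Il1rn -0.17 and Spp1 1.72. Set 2 of random starts gave Mmp12 -0.82 and an Osm difference by Trem2 of -0.987 points, and set 3 a macrophage-like depilation ratio of 0.446. Thinning to 500 UMIs gave a difference by Trem2 of -0.315 points. The resting STAT median was -0.41 with 1 added and -0.17 with TMM scaling, which lowers each log2 ratio by 0.68. The list still stood above 99.85% and 99.92% of random lists. Of dendritic cell-like lists, 2 stood apart with 50 added and 2 with TMM scaling (resting), and of T cell-like lists 1 did without copies of shared barcodes (depilation). Leaving out each library in turn gave 1.27 to 1.75 for Osm in macrophage-like against other immune classes and 0.574 to 8.53 points for Osm by Trem2. Structural cells lower the other shares by construction; elsewhere the cause was not tested.

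No value came from alternatives in which a class had no named cluster or no cells in 1 of the libraries compared: NK cell-like in 7 settings, monocyte-like in 4, Langerhans cell-like at P80 in 5 and neutrophil-like in 1. The random thinning to 1000 UMIs used for Osm ratios left 0 Osm UMIs in P80 and P50_Depil5D and so no Osm ratio.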

Other observations

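Of the tests below, those of shared barcodes, of ribosomal pseudogenes in cluster 32 and in Trem2-positive cells, of Langerhans cell-like cells and of the barcodes of cluster 0 were chosen after the result had been seen, and those of other pseudogenes in cluster 32 and of pseudogenes in cluster 0 before.

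Of the receptor genes for oncostatin M, Osmr was not detected in macrophage-like cells, while Il6st was. Osmr (ENSMUSG00000022146, mm10 chromosome 15, 6813577 to 6874969), encoding the specific receptor chain, had 106 CPM in pericyte or smooth muscle-like cells (65.3 to 161; 21 UMIs) and 30.4 in keratinocyte-like cells (25.9 to 35.4; 163 UMIs). It had 0 UMIs in 405 macrophage-like cells (0 to 3.87 CPM) and 0 in 772 T cell-like cells. Il6st (ENSMUSG00000021756), encoding the signalling chain shared with interleukin-6, had 503 CPM in pericyte or smooth muscle-like cells, 43.0 in macrophage-like and 25.2 in keratinocyte-like cells. These structural cells passed a CD45 sort and stand for few of those in the skin. The pericyte or smooth muscle-like class was cluster 23, led by Ccl21a and Fabp4, with Lrg1, Ly6c1 and Aqp1 also among its leading genes. None of these marks that class, although its markers Acta2, Tagln and Myl9 were among the leading genes too. The Osmr and Il6st levels of the cluster thus cannot be given to pericytes or smooth muscle alone.

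Osm was not limited to the named macrophages. The unnamed cluster 33, with leading genes of neutrophil granules such as S100a9, Ngp and Camp and raised monocyte markers, had an Osm UMI in 28.3% of 46 cells (133 CPM, 77.6 to 213), and 33 of these cells were from P45. Cluster 31, with C1qb, Adgre1 and Trem2 raised and Cxcl2 and Cd14 leading, had one in 15.8% of 57 cells (117 CPM, 69.4 to 185). Of the 196 Osm UMIs in all cells, cluster 33 gave 17, cluster 31 gave 18 and cluster 32 gave 38.

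The first pattern is that P50, P63, P80 and P50_Depil5D shared barcodes. Each pair of these libraries shared 134 to 193, while a pair with P45 shared at most 7, and chance reuse is argued against, since the smallest of the first counts was 19.1 times the largest of the second. Profiles of the same barcode in 2 libraries had a median correlation 0.218 above that of other shared barcodes of the class, which is consistent with molecules of 1 library having been counted in another. Values without these barcodes stand among the alternatives, and no biological explanation was tested.

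The second pattern is cluster 32, macrophage-like, high in Osm and Trem2 and held by P45 (51 of 52 cells). Its ribosomal pseudogene UMIs were 0.296 of those expected from the other P45 macrophage-like cells (0.233 to 0.370), which is consistent with barcodes carried into P45 from another library, though not from 1 of the other 4, with any of which P45 shared at most 7 barcodes. A Trem2-high state with fewer such UMIs is argued against, since P50 macrophage-like cells with Trem2 had 1.04 of the expected number (0.887 to 1.20). Other pseudogenes had 7.73 times the expected number (3.71 to 14.2), which met the condition set beforehand against carried barcodes. That condition was set aside after its value was seen, because each of the 10 UMIs was of Gpr137b-ps. This pseudogene had more UMIs than its parent gene (4) and so is not a stray reading of it. Low-share cells of P45 also made up the unnamed cluster 29, with 8 cells, all of P45 and all low-share. Plasma protein genes such as Serpina1b, Fgb and Ttr were among its leading genes, while cluster 32 had 0 UMIs of Ttr. Whether the cells of cluster 32 belong to P45 skin stays open.

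The third pattern is cluster 0, led by Ctla2a and Areg (the epithelial growth factor amphiregulin) with T cell receptor complex genes such as Cd3e raised, which made up 22.0% of cells in P50 and P50_Depil5D and 1.28% in the other libraries, a ratio of 17.2 (12.5 to 24.1). More epidermis in these 2 digests is argued against as the whole cause, since Langerhans cell-like cells, which live there, had a ratio of 1.78 (1.16 to 2.78). Barcodes carried in from another of the 5 libraries are argued against too, since 0.929% of the cluster's cells in P50 and P50_Depil5D (0.342 to 2.01; 6 of 646) had a barcode also listed elsewhere, against 12.9% of all cells there. Ribosomal pseudogene UMIs at 0.990 of the number expected from T cell-like cells (0.941 to 1.04) also go against P45, P63 and P80, whose higher shares would raise this number, but cannot test carriage between P50 and P50_Depil5D or from a library not among these 5. A difference in age or hair cycle stays open and untested, and it cannot be told apart from a library batch, as P50 and P50_Depil5D also had the same median pseudogene share of 4.17%.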
